A study of Mus musculus with 30 samples.

How the data were processed

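Messenger RNA was measured by poly(A) RNA sequencing of the hypothalamus of diet-induced obese mice, 30 libraries in 5 groups of 6. Per the labels' protocols, total RNA with an integrity number above 7 was made into libraries with the TruSeq RNA Sample Prep kit on an automated liquid handler. This kit does not mark the strand of a transcript. The deposited files hold raw counts of reads per gene, which the authors made with STAR and HTSeq on the mouse build mm9, per the submitters' processing notes. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Each file holds 37310 gene identifiers and 5 HTSeq summary lines.

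The summary lines name no gene and stayed out of library sizes and tests. Across libraries, 42.3% to 42.8% of the reads in a file fell in genes, 42.2% to 42.9% in no gene, 12.7% to 13.7% were not unique and 0.944% to 0.977% were ambiguous between genes. Gene names came from a table of identifiers and symbols, in which 32620 identifiers (87.4%) matched. No genome of the build used by the authors was used here, so positions are not printed. The share of a gene's exons that overlaps another gene came from a newer mouse annotation and is given for genes named where it exceeds 10%, since reads there can belong to either gene.

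Groups came from the source label of each sample. The labels do not say that each sample is a separate mouse, so p-values measure the spread between these samples, which may in part be technical. Replicate numbers follow the accession order and pair nothing. No pair of replicates within a group was a duplicate: the chi-square of their counts per degree of freedom lay between 3.82 and 30.1 over 75 pairs, far above sampling noise.

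Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and robust dispersion estimation. Genes entered when filterByExpr passed them (minimum count 10, minimum total 15), which left 18737. All 30 libraries entered one fit of group means with 25 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at 0.05. With no gene differing, a share of 0.05 of the 18737 tested genes is expected at an unadjusted p under 0.05. There were 8 comparisons: each treatment and the weight clamped group with vehicle, GLP1/Dexa with each of GLP1, Dexa and weight clamped vehicle, and the difference between the GLP1/Dexa effect and the sum of the GLP1 and Dexa effects. Standard errors belong to log2 fold changes of this fit, intervals are 95% intervals, and CPM values are counts scaled to a common library size after TMM.

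The 32 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with a correlation estimated from the data, adjusted over the lists of a comparison. They covered glucocorticoid-induced genes, the stress axis, orexigenic and anorexigenic signals, pituitary control peptides, incretin and glucagon receptors, leptin and insulin signalling, the thyroid axis, immediate-early genes, the unfolded protein response, heat shock, cholesterol synthesis, fasting lipid use, the clock, inflammation and interferon. They also held markers of hypothalamic regions, neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium, mural cells, ependyma with tanycytes, meningeal fibroblasts, choroid plexus, pituitary, cortex with hippocampus, striatum, thalamus and red blood cells. Members past the gene test are given over all genes and adjusted over the list alone. Mean log2 CPM of marker lists and library totals were compared by exact 2-sided permutation tests over 924 assignments, where the smallest p is 0.00216.

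The design, the lists, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule takes the genes with the largest significant rises and falls at 1 CPM or more that keep their direction when any library is left out, members of each list that pass, and 12 genes always named in the comparisons with vehicle (Fkbp5, Tsc22d3, Sgk1, Glp1r, Nr3c1, Agrp, Npy, Pomc, Cartpt, Crh, Hcrt and Pmch). Fewer than the rule allows are named, in order of p, and for the difference from the sum and the comparison with few calls the 5 genes with the smallest p. The other settings fixed then were DESeq2 1.42.0, limma voom, RLE size factors, other count filters, non-robust dispersions, 1 surrogate variable (sva 3.50.0), the library number series as a covariate, only the groups compared, the fry test, and leaving out each library.

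Further alternatives were chosen after seeing the data. One entered a smooth trend of log2 CPM on transcript GC content per library as offsets (Biostrings 2.70.1, rtracklayer 1.62.0; 94.9% of tested genes had a GC value). The next used runs of up to 8 consecutive library numbers, called blocks 1 to 4, as a covariate, with blocks 2 and 3 also joined. Another left out vehicle 2 and GLP1/Dexa 6, the libraries with the highest cortex and pituitary markers. For comparisons with the shared vehicle group, all 30 libraries, vehicle included, were simulated with no changed gene, so that comparisons shared a simulated vehicle group. The real vehicle libraries were also split 3 and 3 in 20 ways.

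The gene test was tested on simulated data for GLP1/Dexa against vehicle over 18737 genes. It recovered 64% of genes changed 1.25-fold, 90% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 9 false calls among 185. The changed genes had a mean of at least 1 CPM. Genes were drawn independently with no block or tissue difference, so these rates may not hold for the real libraries. A simulated GC trend with no changed gene gave 1949 calls, and 0 after GC offsets, which use the same GC values as the simulated trend. Of 100 simulated unchanged lists 0 passed camera, whereas other splits of the real libraries gave medians of 4 to 8 passing lists of 32 per comparison. M stands for 1e+06 reads.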

Results

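Hypothalamic messenger RNA of diet-induced obese mice was sequenced in 30 libraries, 6 from each of 5 groups. Mice received vehicle, the incretin peptide GLP-1 (group GLP1), the synthetic glucocorticoid dexamethasone (Dexa) or a conjugate of both (GLP1/Dexa) for 5 days, each compound at 100 nmol/kg. A further vehicle group was calorie restricted to the body weight of GLP1/Dexa (weight clamped). As a control for weight loss it is limited by library numbers (below). The design text states 5 mice per group, whereas 6 samples per group are deposited. Gene reads per library ranged from 29.15 M to 44.56 M with a median of 39.0 M. Group means were 39.6 M ± 3.35 in vehicle, 40.3 M ± 1.39 in GLP1, 36.6 M ± 3.89 in Dexa, 37.6 M ± 2.07 in GLP1/Dexa and 37.5 M ± 1.80 in weight clamped mice (SD, n = 6 each).

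Library numbers in the labels ran in the order of the groups, and runs of up to 8 consecutive numbers are called blocks 1 to 4 here, a division made after seeing the data. The numbers break off after GLP1/Dexa 5 and resume in a new series with GLP1/Dexa 6, so blocks 3 and 4 hold 7 libraries each. Block 1 held vehicle 1 to 6 and GLP1 1 and 2. Block 2 held GLP1 3 to 6 and Dexa 1 to 4, block 3 held Dexa 5 and 6 and GLP1/Dexa 1 to 5, and block 4 held GLP1/Dexa 6 and the 6 weight clamped libraries. The zinc finger gene Zfp871, chosen for its values, differed between blocks within GLP1 and GLP1/Dexa: GLP1 libraries averaged 2.62 CPM in block 1 and 15.9 CPM in block 2, and the GLP1/Dexa library of block 4 had 2.35 CPM against 14.5 CPM in block 3. In Dexa the gene varied within blocks, from 9.02 to 24.3 CPM in block 2 and from 4.61 to 15.6 CPM in block 3. Within GLP1, 353 genes differed between blocks 2 and 1 (325 higher), and within GLP1/Dexa 129 differed between blocks 3 and 4 (122 higher), where block 4 has 1 library, assumed to vary like the other groups. Dexa, GLP1/Dexa and weight clamped libraries share no block with vehicle. A block term reaches vehicle only through GLP1 1 and 2, and for weight clamped mice also GLP1/Dexa 6. Over the 1572 genes that passed in GLP1/Dexa against vehicle, changes with it were a median of 0.517 and standard errors 2.25 times as large. These calls can thus include a block difference. With a block term, GLP1 is compared with vehicle within block 1 (2 against 6 libraries), GLP1/Dexa with Dexa within block 3 (5 against 2) and GLP1/Dexa with weight clamped within block 4 (1 against 6).

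**Figure D1:**
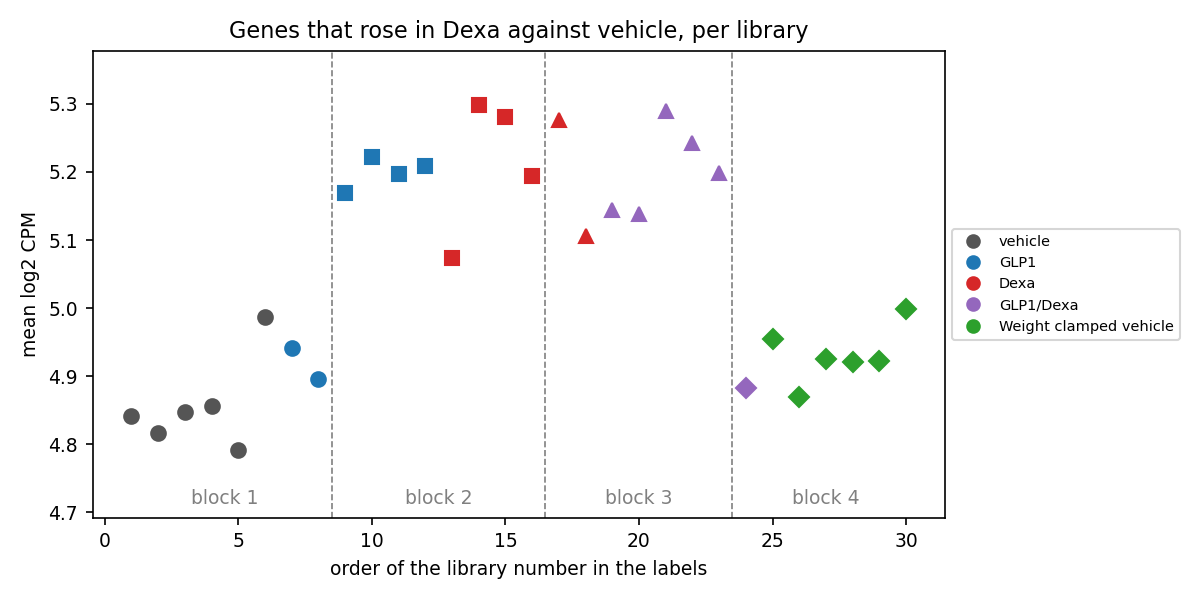
Mean log2 CPM of the 930 genes that rose in Dexa against vehicle, 1 point per library in the order of the library numbers, with the 4 blocks of library numbers marked and colours for the groups. GLP1 libraries averaged 4.92 in block 1 and 5.20 in block 2, beside 4.86 in vehicle and 5.21 in the Dexa libraries of block 2.

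In the hypothalamus of GLP1/Dexa mice 16 of 35 glucocorticoid-induced genes and the lipid-droplet gene Plin4 rose and haemoglobin transcripts fell relative to vehicle. The lists of glucocorticoid-induced and red blood cell genes passed at a preset correlation between genes, but not with an estimated one (adjusted p = 0.104 and 0.127). Fkbp5 (ENSMUSG00000024222), which encodes a co-chaperone of the glucocorticoid receptor, rose from 46.8 ± 5.61 to 67.5 ± 9.52 CPM (SD, n = 6 each), a log2 change of 0.53 ± 0.0872 (SE, adjusted p = 0.000653). The lowest GLP1/Dexa library had 57.0 CPM and the highest vehicle library 54.0 CPM. Plin4, a lipid-droplet coat protein, rose by 1.33 ± 0.221 (adjusted p = 0.000833), and its 6 GLP1/Dexa libraries lay at 52.8 to 74.0 CPM, above the vehicle range of 13.7 to 33.9 CPM. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose 18.3-fold, from 0.363 to 6.77 CPM, with GLP1/Dexa libraries between 0.690 and 16.8 CPM (log2 change 4.19 ± 0.614, adjusted p = 0.000373).

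Other rises were those of Hif3a (0.61 ± 0.0956, adjusted p = 0.000484) and Styx (1.32 ± 0.217, adjusted p = 0.000539), whose exons overlap a gene on the opposite strand over 24.0%. Sgk1, a glucocorticoid-induced kinase, rose by 0.58 ± 0.161 (adjusted p = 0.0267), a call that ended without vehicle 2, 3 or 5 or GLP1/Dexa 4 (adjusted p = 0.0692, 0.0586, 0.0612 and 0.0724). The feeding peptide gene Agrp rose from 2.42 ± 0.768 to 3.51 ± 0.553 CPM (log2 change 0.54 ± 0.165, adjusted p = 0.0365). Its call ended without vehicle 2, 3, 5 or 6 (adjusted p = 0.0795, 0.0836, 0.0656 and 0.0817) or GLP1/Dexa 3, 4 or 5 (0.0701, 0.105 and 0.0690), and 11.3% of its exons overlap a gene on the opposite strand and 11.3% a gene on the same strand. The haemoglobin genes Hbb-bt and Hbb-bs, near-identical copies between which reads can be split, fell by 1.88 ± 0.301 and 1.68 ± 0.287 (adjusted p = 0.000539 and 0.0011). Thbs4 fell by 1.14 ± 0.235 (adjusted p = 0.00328), the early-response gene Egr4 fell by 1.14 ± 0.233 (adjusted p = 0.00308) and Xbp1, a regulator of the unfolded protein response, fell by 0.22 ± 0.0415 (adjusted p = 0.00181). In the fit with blocks, where none passed, Hif3a changed by 0.39, Styx by 0.82, Sgk1 by 0.89 (adjusted p = 0.882 each) and Xbp1 by -0.13 (adjusted p = 0.887).

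**Figure D2:**
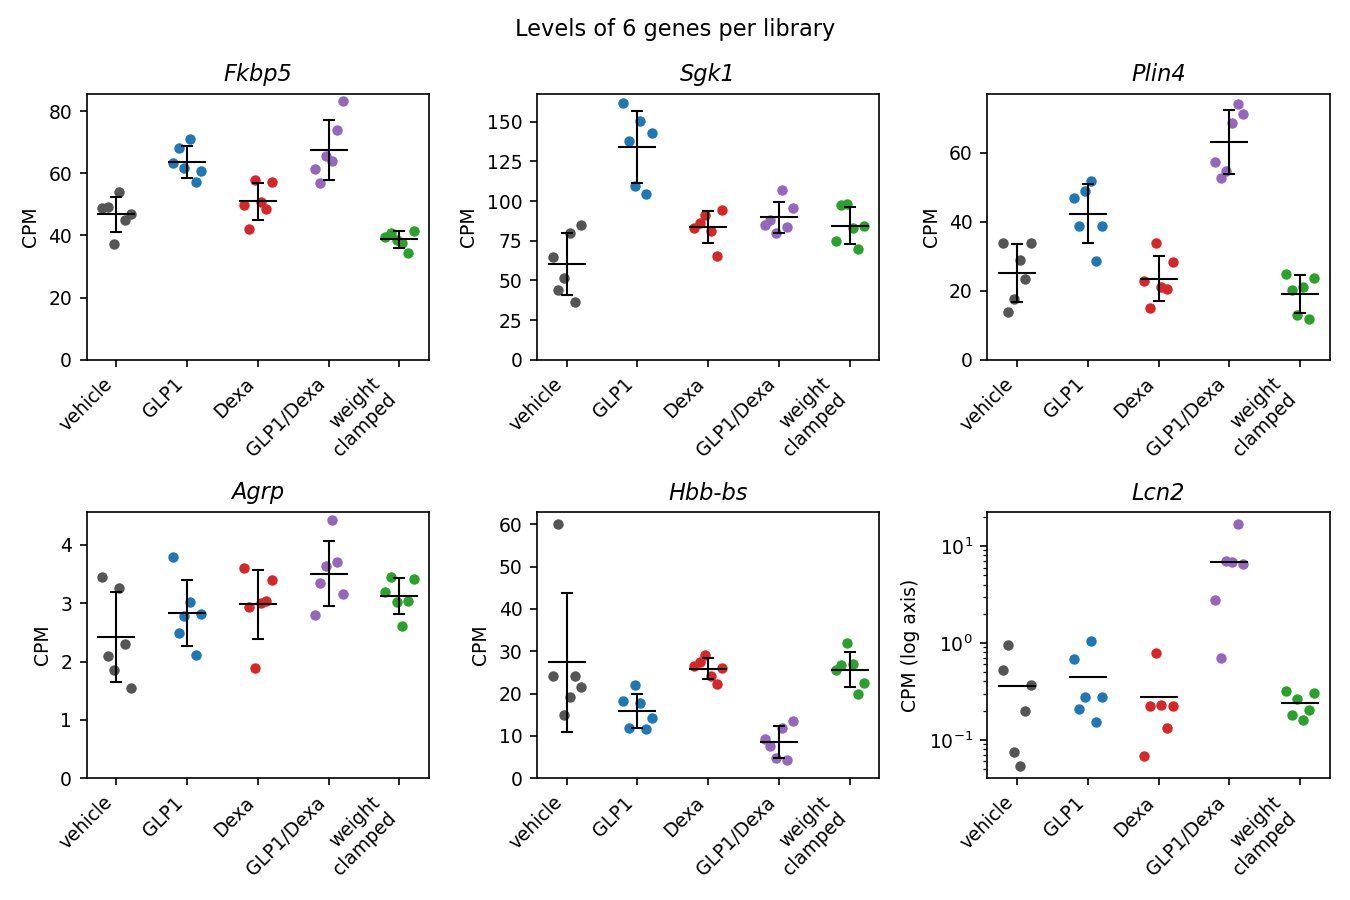
CPM of Fkbp5, Sgk1, Plin4, Agrp, Hbb-bs and Lcn2 in each library of the 5 groups, with the mean and SD of 6 libraries, and for Lcn2 the mean on a log axis. Plin4 in the 6 GLP1/Dexa libraries lies at 52.8 to 74.0 CPM, above all vehicle, GLP1, Dexa and weight clamped libraries.

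Against vehicle 1572 genes changed in GLP1/Dexa, 1066 up and 506 down, with a median change of 1.17-fold and 80 genes over 2-fold. With GC offsets 57.5% of the calls were higher, against 67.8% without them. Of 35 glucocorticoid-induced genes 16 rose, 0 fell and 19 did not pass, and adjusted over the list alone 23 passed (median 0.24, camera adjusted p = 9.6e-16, adjusted p = 0.104 with an estimated correlation). Of 18 immediate-early genes 0 rose, 10 fell and 8 did not pass. The number adjusted over the list alone was 11 (median -0.37, camera adjusted p = 5.43e-07, adjusted p = 0.104 with an estimated correlation). Without vehicle 2, which had the highest cortex and hippocampus markers, 5 of these genes fell in GLP1/Dexa, 2 in GLP1, 3 in Dexa and 4 in weight clamped mice, against 10, 4, 5 and 6 with it. The list medians were then -0.24, -0.22, -0.22 and -0.16, and the list still passed in all 4 (camera adjusted p = 2.22e-06, 1.34e-06, 1.46e-05 and 0.000356). Of 18 genes of the unfolded protein response 0 rose, 7 fell and 11 did not pass. Adjusted over the list alone, 9 passed (median -0.14, camera adjusted p = 2.16e-07, adjusted p = 0.104 with an estimated correlation). All 3 red blood cell genes fell, over all genes and adjusted over the list alone (median -1.68, camera adjusted p = 0.000197, adjusted p = 0.127 with an estimated correlation).

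Several appetite and stress genes did not pass in GLP1/Dexa: Tsc22d3 (0.21, adjusted p = 0.0794), Npy (-0.32, adjusted p = 0.167), Glp1r (-0.24, adjusted p = 0.268), Pomc (0.57, adjusted p = 0.411), Cartpt (-0.18, adjusted p = 0.411), Crh (-0.12, adjusted p = 0.692), Nr3c1 (0.04, adjusted p = 0.742), Hcrt (-0.07, adjusted p = 0.823) and Pmch (0.02, adjusted p = 0.923; 58.1% of its exons overlap a gene on the opposite strand). The Pomc value rests on GLP1/Dexa 6, at 186 CPM against 20.8 to 35.7 CPM in the other 5 libraries and a vehicle mean of 36.5 CPM, and without that library Pomc changed by -0.42 (adjusted p = 0.185). That library also had the highest mean of pituitary markers, at 1.83 log2 CPM, and the pituitary gene Prl, chosen after its values were seen, at 13.2 CPM against at most 0.292 CPM in the other 5. Tsc22d3 passed without vehicle 1 (adjusted p = 0.00866) and with DESeq2, and Npy without vehicle 6 (adjusted p = 0.0464). With the block term, in which vehicle is reached only through other groups, edgeR called 0 genes against vehicle (1007 at an unadjusted p under 0.05; without that term limma voom called 1412 and DESeq2 1953), and Fkbp5 changed by 0.45 ± 0.192 (adjusted p = 0.882). The glucocorticoid-induced list had a median of 0.29 with the block term (camera adjusted p = 3.78e-14), the unfolded protein response and red blood cell lists passed (adjusted p = 0.000779 and 0.0013), and the immediate-early list did not (0.0517), though it did with blocks 2 and 3 joined (0.00218). With only these groups in the fit 698 genes passed, and without GLP1/Dexa 3, 4 or 5 the numbers were 815, 884 and 1012. The number of lists that passed was 4, and 7 without vehicle 5 or without GLP1/Dexa 4.

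Under GLP-1 alone glucocorticoid-induced genes rose relative to vehicle. Sgk1 rose from 60.2 ± 19.6 to 134 ± 22.8 CPM (SD, n = 6 each), a log2 change of 1.16 ± 0.161 (adjusted p = 0.000212), with the lowest GLP1 library at 104 CPM and the highest vehicle library at 85.0 CPM. Arrdc2 rose by 0.96 ± 0.0959 (adjusted p = 4.76e-07), Ddit4, an inhibitor of mTORC1 signalling, rose by 0.46 ± 0.0653 (adjusted p = 0.000137) and Fkbp5 by 0.45 ± 0.0872 (adjusted p = 0.00817). Arl4d rose by 1.07 ± 0.134 (adjusted p = 2.48e-05), and Cldn5, a tight-junction protein of endothelium, fell by 0.61 ± 0.0814 (adjusted p = 6.15e-05). Within block 1 Arrdc2 rose by 1.04 ± 0.131 (adjusted p = 0.000324), Sgk1 by 1.31 ± 0.219 (adjusted p = 0.00717), and Fkbp5 changed by 0.49 ± 0.112 without passing (adjusted p = 0.0978).

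Tsc22d3 rose by 0.34 ± 0.0760 in GLP1 (adjusted p = 0.0244), a call that ended without vehicle 2, 3 or 5 or GLP1 4 (adjusted p = 0.0694, 0.068, 0.0752 and 0.0783). Gldc fell by 0.53 ± 0.0991 (adjusted p = 0.00409), and the immediate-early genes Egr1 and Junb each fell by 0.51 (SE 0.1 and 0.105, adjusted p = 0.00748 and 0.01). The microglial receptor Cx3cr1 fell by 0.29 ± 0.0469 (adjusted p = 0.000594). Within block 1 none of these passed, with larger standard errors. Tsc22d3 changed by 0.44 (adjusted p = 0.139), Gldc by -0.48 (0.468), Egr1 by -0.46 (0.628), Junb by -0.56 (0.285) and Cx3cr1 by -0.21 (0.468). Without the block term Npy (-0.31, adjusted p = 0.289), Nr3c1 (0.09, 0.552), Agrp (0.23, 0.566), Glp1r (-0.18, 0.575) and Cartpt (-0.15, 0.639) did not pass. Nor did Crh (0.17, 0.692), Pomc (-0.14, 0.920), Hcrt (-0.03, 0.952) and Pmch (0.01, 0.971).

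In GLP1 against vehicle 233 genes changed, 175 up and 58 down, with a median change of 1.22-fold. Of 35 glucocorticoid-induced genes 14 rose, 0 fell and 21 did not pass, and adjusted over the list alone 23 passed (median 0.25, camera adjusted p = 3.89e-30, adjusted p = 0.00793 with an estimated correlation). Within block 1 the median was 0.35 (camera adjusted p = 6.85e-43). Of the 18 immediate-early genes 4 fell and 0 rose. Those passing adjusted over the list alone numbered 10 (median -0.29, camera adjusted p = 1.61e-07, adjusted p = 0.0948 with an estimated correlation, within block 1 adjusted p = 0.000131). The unfolded protein response (median -0.12, camera adjusted p = 7.4e-05), heat shock genes (median -0.13, camera adjusted p = 0.000292) and red blood cell genes (median -0.78, camera adjusted p = 0.0177) had 0 members past the gene test and 7, 2 and 3 adjusted over the list alone. With an estimated correlation they had adjusted p = 0.386, 0.412 and 0.412, and within block 1 adjusted p = 0.0201, 1.48e-05 and 0.0216.

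Cholesterol synthesis genes lay higher in GLP1 (median 0.07, camera adjusted p = 0.000615, 0 members passed, 2 adjusted over the list alone) and microglial genes lower (median -0.05, camera adjusted p = 0.0471, 1 fell, 0 rose, 1 adjusted over the list alone). With an estimated correlation these had adjusted p = 0.412 and 0.798, and within block 1 adjusted p = 0.0556 and 0.832. The cholesterol call ended without vehicle 6 (adjusted p = 0.0508), the microglial call without vehicle 1, 2 or 6 or GLP1 6 (adjusted p = 0.115, 0.284, 0.207 and 0.302) and the red blood cell call without vehicle 2 or GLP1 2 (adjusted p = 0.111 and 0.0738). Within block 1 28 genes passed, 26 of them among the 233 (1059 at an unadjusted p under 0.05), with only these groups in the fit 37 and with no filter on low counts 154. Leaving out 1 library moved the number of changed genes between 58 and 635: without vehicle 1 to 6 it was 148, 86, 106, 152, 100 and 534, and without GLP1 1 to 6 it was 577, 635, 108, 58, 112 and 75.

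Under dexamethasone alone few glucocorticoid-induced genes changed relative to vehicle. Nfkbia, a glucocorticoid-responsive inhibitor of NF-kappaB, rose by 0.35 ± 0.0933 (adjusted p = 0.0206), a call that ended without vehicle 2 or 5 or Dexa 2 or 6 (adjusted p = 0.0517, 0.0592, 0.0519 and 0.0519). Fkbp5 did not pass (51.0 ± 5.93 CPM, SD, n = 6; log2 change 0.13 ± 0.0877, adjusted p = 0.468). The receptor gene Nr3c1 rose by 0.20 ± 0.0604 (adjusted p = 0.0469), and did not pass with blocks (0.10, adjusted p = 0.947), GC offsets (adjusted p = 0.155), a surrogate variable, no filter on low counts or limma voom, or without any of vehicle 1 to 5 (adjusted p = 0.0832, 0.0845, 0.0924, 0.0713 and 0.0778) or Dexa 2 to 4 (0.148, 0.0958 and 0.0842). The endoplasmic reticulum chaperone Calr fell by 0.21 ± 0.0447 (adjusted p = 0.00475), and the early-response genes Junb and Fosl2 fell by 0.51 ± 0.106 and 0.37 ± 0.0827 (adjusted p = 0.00475 and 0.00687).

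Lmbrd2 rose by 2.17 ± 0.405 in Dexa (adjusted p = 0.0037) and Klhl11 by 2.23 ± 0.446 (adjusted p = 0.00477), whereas with the block term they changed by 0.19 ± 0.456 and -0.062 ± 0.539. Ankrd63 fell by 2.15 ± 0.434 (adjusted p = 0.00475), which limma voom did not call. Not passing were Sgk1 (0.47 ± 0.161, adjusted p = 0.0802), Tsc22d3 (0.20, 0.132), Crh (-0.31, 0.289), Agrp (0.30, 0.323) and Glp1r (-0.17, 0.534). Nor did Npy (-0.17, 0.563), Hcrt (-0.13, 0.718), Pmch (0.08, 0.784), Pomc (0.10, 0.937) and Cartpt (-0.01, 0.984) pass. Sgk1 passed without vehicle 4 or 6 (adjusted p = 0.0408 and 0.0204), with non-robust dispersions, a surrogate variable or DESeq2, and Tsc22d3 without vehicle 1 (adjusted p = 0.0176).

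In Dexa against vehicle 1209 genes changed, 930 up and 279 down, with a median change of 1.17-fold. Of 18 genes of the unfolded protein response 6 fell and 0 rose. A total of 9 passed adjusted over the list alone (median -0.14, camera adjusted p = 2.2e-07). Of 18 immediate-early genes 5 fell and 0 rose. When adjusted over the list alone, the number was 8 (median -0.36, camera adjusted p = 2.59e-06). Both had adjusted p = 0.173 with an estimated correlation. Of 12 heat shock genes 2 fell and 0 rose. The count adjusted over the list alone was 6 (median -0.15, camera adjusted p = 2.17e-05, adjusted p = 0.326 with an estimated correlation). Of 17 cholesterol synthesis genes 2 rose and 0 fell. The number adjusted over the list alone was 4 (median 0.11, camera adjusted p = 0.000578, adjusted p = 0.426 with an estimated correlation). Of 35 glucocorticoid-induced genes 3 rose and 0 fell. Adjusted over the list alone, 5 passed (median 0.07, camera adjusted p = 0.0124, adjusted p = 0.960 with an estimated correlation).

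Choroid plexus markers lay lower in Dexa (median -1.96, 0 passed, 0 adjusted over the list alone, camera adjusted p = 0.0407, adjusted p = 0.966 with an estimated correlation). In the fit with blocks their median was 1.13, in the opposite direction (adjusted p = 0.174), and the call ended without vehicle 4 or 6 (adjusted p = 0.373 and 0.306) or Dexa 1, 2, 5 or 6 (0.104, 0.0744, 0.0573 and 0.149). The other 5 lists passed in the fit with blocks: the unfolded protein response (adjusted p = 0.00148), immediate-early genes (0.0133), heat shock (1.52e-07), cholesterol synthesis (0.0477) and glucocorticoid-induced genes (median 0.16, 1.52e-07). With blocks 2 and 3 joined cholesterol synthesis did not pass (0.152). The glucocorticoid call ended without vehicle 3 or 5 or Dexa 6 (adjusted p = 0.0974, 0.0845 and 0.171). The 930 genes that rose had a median GC content of 42.7% and the 279 that fell 56.1%, against 49.8% over the tested genes, and with GC offsets 718 genes passed, 493 up and 225 down. A block term left 0 genes in edgeR (1044 at an unadjusted p under 0.05; without that term limma voom called 1159 and DESeq2 1550), and without vehicle 2, Dexa 2 or Dexa 3 the numbers were 771, 721 and 684.

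In calorie restricted mice at the weight of the conjugate group heat shock and unfolded protein response genes fell and cholesterol synthesis genes rose relative to vehicle. Lss and Fdps, enzymes of sterol and isoprenoid synthesis, rose by 0.30 ± 0.0466 and 0.27 ± 0.0516 (adjusted p = 0.000473 and 0.00303), and 26.7% of Fdps exons overlap a gene on the same strand. The chaperone Hspa8 fell by 0.19 ± 0.0320 (adjusted p = 0.00113), Calr by 0.27 ± 0.0447 (adjusted p = 0.000718) and the glutamine synthetase gene Glul fell by 0.42 ± 0.0513 (adjusted p = 5.23e-05). The clock genes Ciart and Per3 rose by 0.51 ± 0.0672 and 0.23 ± 0.0444 (adjusted p = 8.13e-05 and 0.00286). Irs2, an insulin receptor substrate, fell by 0.30 ± 0.0555 (adjusted p = 0.00254), Fosl2 fell by 0.52 ± 0.0830 (adjusted p = 0.000599), Gpr17 fell by 0.31 ± 0.0548 (adjusted p = 0.00169), and Wdr27 rose by 0.68 ± 0.103 (adjusted p = 0.000414). Cstad rose by 0.75 ± 0.145 (adjusted p = 0.00303), but changed by -0.078 ± 0.418 with the block term, and Per3 by 0.09 (adjusted p = 0.916).

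Glp1r fell from 3.87 ± 0.983 to 2.73 ± 0.263 CPM in weight clamped mice (SD, n = 6 each; log2 change -0.50 ± 0.132, adjusted p = 0.0260). Its call ended without vehicle 1 or 6 (adjusted p = 0.0892 and 0.0624) or weight clamped 3, 4 or 6 (0.0552, 0.0645 and 0.0507), and limma voom did not call it. Not passing were Fkbp5 (-0.27, adjusted p = 0.0807), Sgk1 (0.49, 0.0878), Crh (-0.43 ± 0.159, 0.121), Agrp (0.37, 0.214) and Hcrt (-0.25, 0.406). Nor did Cartpt (-0.17, 0.506), Npy (-0.16, 0.600), Nr3c1 (0.06, 0.660), Tsc22d3 (-0.06, 0.754), Pmch (0.04, 0.903) and Pomc (-0.38, 0.676) pass. Pomc changed by -3.28 with the block term (adjusted p = 0.0627) and passed with blocks 2 and 3 joined (-3.28, adjusted p = 0.00437) and with the library number series (-3.15, adjusted p = 5.98e-05). The block fits reach vehicle from block 4 only through GLP1/Dexa 6, which had 186 CPM. Fkbp5 passed without vehicle 3 (adjusted p = 0.0248), Sgk1 passed without vehicle 4 or 6 (adjusted p = 0.0450 and 0.0284) and with a surrogate variable, and DESeq2 called both.

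Weight clamped mice differed from vehicle in 744 genes, 314 up and 430 down, with a median change of 1.15-fold. Of 12 heat shock genes 9 fell and 0 rose, and adjusted over the list alone all 12 passed (median -0.25, camera adjusted p = 4.72e-13). Of 17 cholesterol synthesis genes 8 rose and 0 fell. Those passing adjusted over the list alone numbered 13 (median 0.12, camera adjusted p = 2.32e-12). Of 18 genes of the unfolded protein response 11 fell and 0 rose. A total of 11 passed adjusted over the list alone (median -0.17, camera adjusted p = 4.19e-12). Of 12 astrocyte markers 4 fell and 0 rose. When adjusted over the list alone, the number was 6 (median -0.12, camera adjusted p = 0.00203). Of 10 thyroid axis genes 1 fell and 0 rose. The count adjusted over the list alone was 6 (median -0.15, camera adjusted p = 0.00259). These 5 lists had adjusted p = 0.0116 with an estimated correlation. Of 16 leptin and insulin signalling genes 3 fell and 0 rose. The number adjusted over the list alone was 4 (median -0.06, camera adjusted p = 0.00203, adjusted p = 0.0201 with an estimated correlation).

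Further lists passed only with the preset correlation in weight clamped mice. Of 16 clock genes 4 rose and 0 fell. Adjusted over the list alone, 4 passed (median 0.06, camera adjusted p = 0.00476, adjusted p = 0.122 with an estimated correlation). Of 7 oligodendrocyte precursor markers 2 fell and 0 rose. Those passing adjusted over the list alone numbered 3 (median -0.11, camera adjusted p = 0.00476, adjusted p = 0.101 with an estimated correlation). Of 18 immediate-early genes 6 fell and 0 rose. A total of 6 passed adjusted over the list alone (median -0.25, camera adjusted p = 5.69e-05, adjusted p = 0.106 with an estimated correlation). Of 16 microglial markers 2 fell and 0 rose. When adjusted over the list alone, the number was 3 (median -0.09, camera adjusted p = 0.00515, adjusted p = 0.387 with an estimated correlation). Of 35 glucocorticoid-induced genes 2 rose and 4 fell, and adjusted over the list alone 4 rose and 11 fell (median -0.13, camera adjusted p = 0.00971, adjusted p = 0.498 with an estimated correlation). Of 9 cortex and hippocampus markers 2 fell and 0 rose. The count adjusted over the list alone was 2 (median -0.54, camera adjusted p = 0.0263, adjusted p = 0.416 with an estimated correlation). Of 13 fasting lipid genes 0 passed. The number adjusted over the list alone was 1 (median -0.10, camera adjusted p = 0.0382, adjusted p = 0.111 with an estimated correlation).

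In the fit with blocks the heat shock (adjusted p = 0.000199), cholesterol synthesis (1.52e-05), unfolded protein response (0.0042) and clock lists (0.00245) passed in weight clamped mice against vehicle. The astrocyte (median -0.08, 0.605), thyroid axis (-0.18, 0.0974), leptin and insulin (-0.11, 0.247) and precursor lists (-0.09, 0.231) did not. Nor did the immediate-early (-0.18, 0.247), glucocorticoid (-0.13, 0.0974), microglial (-0.05, 0.959), cortex (-0.70, 0.110) and fasting lipid lists (-0.06, 0.412). With blocks 2 and 3 joined the thyroid axis (0.0470), glucocorticoid (0.0362) and cortex lists (0.00231) passed as well. The cortex and microglial calls ended without vehicle 2 (adjusted p = 0.492 and 0.0527), and the glucocorticoid call without vehicle 1 or 6 or weight clamped 5 (0.0580, 0.0589 and 0.0699). The fasting lipid call ended without vehicle 1, 4 or 5 (adjusted p = 0.0580, 0.0965 and 0.0506) or weight clamped 2, 3 or 5 (0.0502, 0.0584 and 0.0938). A block term left 0 genes in edgeR (1371 at an unadjusted p under 0.05), and the series of library numbers as a covariate left 2 (2341 at an unadjusted p under 0.05). Over the 744 genes changes were a median of 0.969 times as large with the block term and 0.991 with the series. Their standard errors were a median of 3.01 and 2.14 times as large, so precision fell while the changes stayed about as large. Without these terms limma voom called 687 and DESeq2 1070. Without weight clamped 2, 3 or 4 the numbers in edgeR were 494, 482 and 427.

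**Figure D3:**
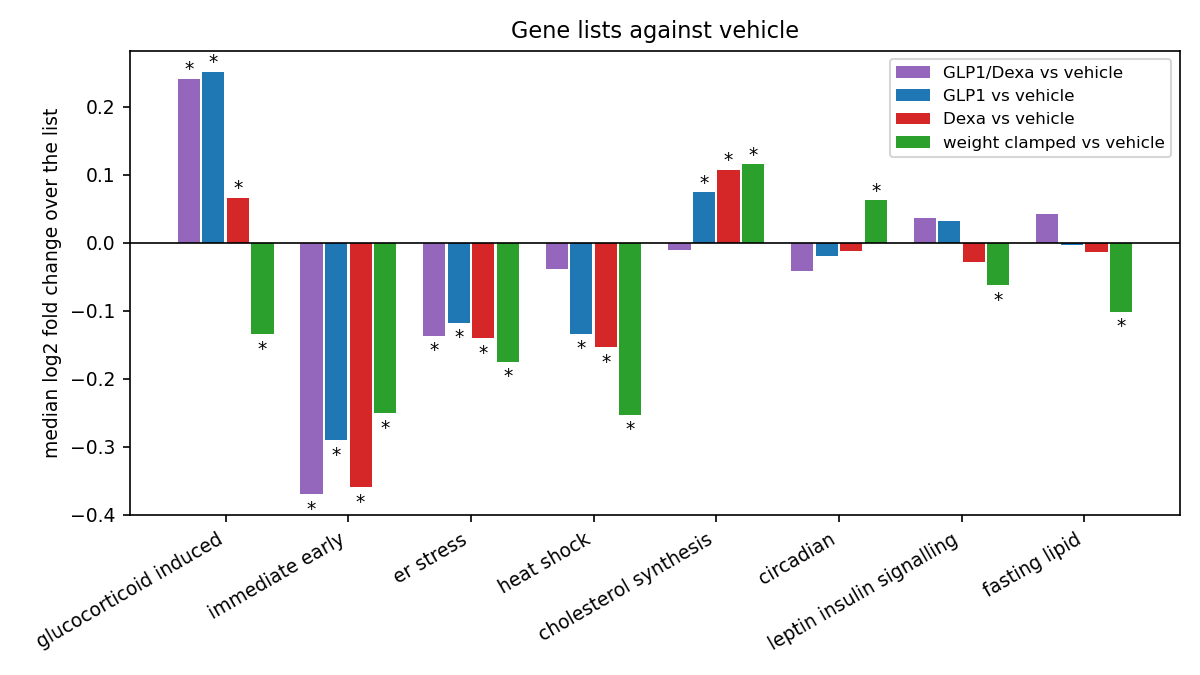
Median log2 fold change of 8 gene lists in the 4 comparisons with vehicle, with an asterisk where camera gave an adjusted p under 0.05 at the preset correlation. The glucocorticoid-induced list has medians of 0.24 in GLP1/Dexa, 0.25 in GLP1, 0.07 in Dexa and -0.13 in weight clamped mice.

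Few genes passed between the conjugate and GLP-1 alone at the same dose. Lcn2 was higher by 3.94 ± 0.600 in GLP1/Dexa (adjusted p = 0.00569) and Sox9, a transcription factor of glia, by 0.35 ± 0.0601 (adjusted p = 0.0111), while Plpp3 was lower (-0.18 ± 0.0289, adjusted p = 0.00569; n = 6 each). Cldn5 (0.42 ± 0.0818) and Cttnbp2nl (-0.22 ± 0.0441) did not pass (adjusted p = 0.0622 each), though Cldn5 passed without GLP1 3 or 4 or GLP1/Dexa 2 or 4 (adjusted p = 0.0273, 0.0433, 0.0434 and 0.0456). DESeq2 called Cldn5 and Cttnbp2nl, and limma voom did not call Lcn2. In the fit with blocks Lcn2 differed by 4.85, Sox9 by 0.24 and Plpp3 by -0.12 (adjusted p = 0.928 each). The 95% interval of the difference was -0.09 to 0.26 for Fkbp5 (0.08, adjusted p = 0.887) and -0.91 to -0.25 for Sgk1 (-0.58, adjusted p = 0.259). It was -0.28 to 0.03 for Tsc22d3, -0.02 to 0.64 for Agrp and -0.33 to 0.21 for Glp1r.

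Between GLP1/Dexa and GLP1 3 genes passed (2 up, 1 down; 1436 at an unadjusted p under 0.05), with 2 by limma voom and 37 by DESeq2. With GC offsets 40.0% of the calls were higher, against 66.7% without them. In the 5 lists that passed, 0 members passed the gene test. Cholesterol synthesis genes were lower in GLP1/Dexa (median -0.07, 5 adjusted over the list alone, camera adjusted p = 1.87e-06, adjusted p = 0.458 with an estimated correlation), as were red blood cell genes (median -0.89, 2 adjusted over the list alone, camera adjusted p = 0.00349, adjusted p = 0.458 with an estimated correlation). Oligodendrocyte genes (median -0.11, 0 adjusted over the list alone, camera adjusted p = 0.00349, adjusted p = 0.817 with an estimated correlation), clock genes (median -0.04, 3 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.458 with an estimated correlation) and the unfolded protein response (median -0.04, 1 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.789 with an estimated correlation) were lower too. The glucocorticoid-induced list did not pass (camera adjusted p = 0.129, adjusted p = 0.908 with an estimated correlation), with a median of -0.07 and a mean of 0.08 that differ in sign and 11 members adjusted over the list alone, 3 up and 8 down.

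No block holds both GLP1/Dexa and GLP1. A block term left 0 genes in edgeR (944 at an unadjusted p under 0.05), and with blocks 2 and 3 joined, 5 GLP1/Dexa against 4 GLP1 libraries, it called 0 (1042 at an unadjusted p under 0.05). By chance a share of 0.05 of tested genes has such a p, close to the former number. In the fit with blocks the oligodendrocyte and clock lists had medians of 0.05 and -0.013 and did not pass (adjusted p = 0.615 and 0.816), cholesterol synthesis did not pass (0.329), and the red blood cell and unfolded protein response lists passed (0.0428 and 0.0333). With blocks 2 and 3 joined cholesterol synthesis and red blood cell genes passed (3.98e-06 and 0.00402), and the unfolded protein response did not (0.196). The clock call ended without GLP1 2 or 6 or GLP1/Dexa 5 (adjusted p = 0.0628, 0.0611 and 0.0735), the unfolded protein response call without GLP1 1 or 3 or GLP1/Dexa 1 or 2 (0.1, 0.0519, 0.109 and 0.145), and the oligodendrocyte call without GLP1/Dexa 3 or 5 (0.0525 and 0.0756). Without GLP1/Dexa 5 the number of lists that passed was 3, against 5. Without GLP1 3, 4 or 6 or GLP1/Dexa 2 the gene numbers were 7, 9, 6 and 5, and with only these groups in the fit edgeR called 0 (1265 at an unadjusted p under 0.05).

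Of 35 glucocorticoid-induced genes 9 were higher under the conjugate than under dexamethasone alone at the same dose, and as a list they did not pass with an estimated correlation (adjusted p = 0.184). Fkbp5 was higher in GLP1/Dexa by 0.40 ± 0.0871 (95% interval 0.23 to 0.58, adjusted p = 0.0193; n = 6 each), Sgk3 by 0.71 ± 0.0970 (adjusted p = 0.000263), Plin4 by 1.42 ± 0.222 (adjusted p = 0.00316) and Lcn2 by 4.57 ± 0.643 (adjusted p = 0.000728). The lowest GLP1/Dexa library for Plin4 had 52.8 CPM and the highest Dexa library 33.8 CPM. Limma voom did not call Lcn2 here. Ednrb was lower (-0.43 ± 0.0737, adjusted p = 0.00555), as were Serpinb1a (-0.71 ± 0.126, adjusted p = 0.00555), Hbb-bt (-1.71 ± 0.303, adjusted p = 0.00586) and Fdps (-0.26 ± 0.0522, adjusted p = 0.00952). The interval was -0.22 to 0.43 for Sgk1 (0.10), -0.28 to -0.03 for Nr3c1 (-0.16, adjusted p = 0.25) and -0.09 to 0.57 for Agrp (0.24). Within block 3 Fkbp5 differed by 0.28 ± 0.119 (adjusted p = 0.460), and with blocks 2 and 3 joined by 0.33 ± 0.0839 (adjusted p = 0.0582), passing in neither. Within block 3 Sgk3 differed by 0.66 ± 0.148 (adjusted p = 0.0971), Plin4 by 1.33 ± 0.357 (adjusted p = 0.214) and Lcn2 by 5.23 ± 1.18 (adjusted p = 0.110), and with blocks 2 and 3 joined all 3 passed (adjusted p = 0.00192, 0.0104 and 0.00255). Of the lower genes, Serpinb1a differed within block 3 by -0.41 (adjusted p = 0.419), Ednrb by -0.32 (0.336), Hbb-bt by -1.94 (0.0971) and Fdps by -0.20 (0.381), and with these blocks joined they passed (0.0104, 0.0185, 0.0132 and 0.0243).

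Between GLP1/Dexa and Dexa 150 genes passed, 88 up and 62 down, with a median difference of 1.21-fold. Among the 35 glucocorticoid-induced genes 9 were higher and 0 lower. Adjusted over the list alone, 16 passed (median 0.16, camera adjusted p = 3.06e-12, adjusted p = 0.184 with an estimated correlation, within block 3 median 0.15, adjusted p = 4.83e-06). Of 3 red blood cell genes 2 were lower. Those passing adjusted over the list alone numbered 3 (median -1.59, camera adjusted p = 7.46e-07, adjusted p = 0.0784 with an estimated correlation, within block 3 median -1.67, adjusted p = 1.76e-05). Of 17 cholesterol synthesis genes 2 were lower and 0 higher. A total of 6 passed adjusted over the list alone (median -0.07, camera adjusted p = 1.4e-06, adjusted p = 0.184 with an estimated correlation). Of 12 oligodendrocyte genes 1 was lower and 0 higher. When adjusted over the list alone, the number was 4 (median -0.18, camera adjusted p = 3.21e-05, adjusted p = 0.854 with an estimated correlation). Within block 3 these had adjusted p = 0.0919 and 0.220, and with blocks 2 and 3 joined 3.87e-05 and 0.000154. Within block 3 the genes that passed were 5 others, named after their values were seen (Nmbr, Gckr, Oprm1, Snx31 and D130058E05Rik), and 0 of the 150 did (1767 genes at an unadjusted p under 0.05 in edgeR; limma voom called 132 and DESeq2 313 without blocks). With blocks 2 and 3 joined 127 passed, 104 of them among the 150, and with only these groups in the fit 66. Without Dexa 2, 3, 4 or 6 it was 65, 96, 97 and 273, and without GLP1/Dexa 3, 4 or 5 it was 69, 88 and 92.

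Against weight clamped mice, which were matched for weight without a compound, glucocorticoid-induced genes as a list were higher in GLP1/Dexa and cholesterol synthesis genes lower. The cholesterol synthesis list passed with higher values in weight clamped mice against vehicle (median 0.115, camera adjusted p = 2.32e-12), but did not pass in GLP1/Dexa against vehicle. Zbtb16 was higher by 1.14 ± 0.109 (adjusted p = 1.13e-06), Cdkn1a, a cell-cycle inhibitor, by 1.23 ± 0.128 (adjusted p = 1.38e-06), Plin4 by 1.73 ± 0.225 (adjusted p = 3.65e-05) and Lcn2 by 4.81 ± 0.655 (adjusted p = 5.54e-05; n = 6 each). Fkbp5 was higher by 0.80 (95% interval 0.62 to 0.98, adjusted p = 2.94e-06), the lowest GLP1/Dexa library having 57.0 CPM and the highest weight clamped library 41.5 CPM. Sgk1 and Agrp, which passed in GLP1/Dexa against vehicle, did not pass here. Sgk1 differed by 0.09 (95% interval -0.24 to 0.42, adjusted p = 0.801) and Agrp by 0.17 (-0.16 to 0.50, adjusted p = 0.59). The lipid genes Angptl4 and Pnpla2 were higher by 1.08 ± 0.138 and 0.39 ± 0.0637 (adjusted p = 8.76e-06 and 0.000241), and Fdps lower (-0.40 ± 0.0520, adjusted p = 8.76e-06). The clock gene Dbp was lower (-0.35 ± 0.0571, adjusted p = 0.000219; 18% of its exons overlap a gene on the opposite strand), as was the oligodendrocyte gene Opalin (-0.75 ± 0.132, adjusted p = 0.000895).

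Further genes higher in GLP1/Dexa than in weight clamped mice were the chaperone gene Hsph1 (0.44 ± 0.0732, adjusted p = 0.000496) and the insulin and IGF-1 receptors Insr (0.22 ± 0.0472, adjusted p = 0.00319) and Igf1r (0.29 ± 0.0540, adjusted p = 0.00122). Within block 4, where GLP1/Dexa 6 is set against 6 weight clamped libraries, Zbtb16 differed by 1.34 and Cdkn1a by 1.51 (adjusted p = 0.000757 each), Plin4 by 1.91 ± 0.378 (adjusted p = 0.0367), Lcn2 by 4.77 ± 0.920 (adjusted p = 0.0285) and Angptl4 by 1.13 (adjusted p = 0.0445). A single library shows no spread of its own, and these standard errors take it from the other groups. Not passing within block 4 were Insr (0.038, adjusted p = 0.940), Igf1r (0.15, adjusted p = 0.683), Hsph1 (0.26, adjusted p = 0.627), Dbp (-0.19, adjusted p = 0.667), Fdps (-0.39, adjusted p = 0.133), Opalin (-0.86, adjusted p = 0.376) and Pnpla2 (0.42, adjusted p = 0.164). Kcna3 and Fam135b, higher by 2.40 ± 0.512 and 1.66 ± 0.305 (adjusted p = 0.00484 and 0.00132), differed within block 4 by -0.77 ± 0.771 and 0.18 (adjusted p = 0.947 for Fam135b), and limma voom did not call Kcna3.

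Between GLP1/Dexa and weight clamped mice 1592 genes passed, 997 up and 595 down, with a median difference of 1.17-fold. Among the 35 glucocorticoid-induced genes 19 were higher and 1 lower. The count adjusted over the list alone was 25 (median 0.35, camera adjusted p = 1.52e-21, adjusted p = 0.0195 with an estimated correlation, within block 4 adjusted p = 9.18e-30). Of 17 cholesterol synthesis genes 9 were lower and 0 higher. The number adjusted over the list alone was 12 (median -0.14, camera adjusted p = 9.05e-12, adjusted p = 0.0195 with an estimated correlation, within block 4 median -0.19). Of 16 leptin and insulin signalling genes 6 were higher and 0 lower. Adjusted over the list alone, 7 passed (median 0.11, camera adjusted p = 3.62e-05, adjusted p = 0.0101 with an estimated correlation, within block 4 median 0.039). Of 16 clock genes 1 was higher and 7 lower. Those passing adjusted over the list alone numbered 9 (median -0.12, camera adjusted p = 6.22e-05, adjusted p = 0.0427 with an estimated correlation, within block 4 median -0.112).

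Heat shock genes were also higher in GLP1/Dexa than in weight clamped mice, 5 of 12 by the gene test and 0 lower, with 8 adjusted over the list alone, 7 up and 1 down (median 0.18, camera adjusted p = 6.22e-05, adjusted p = 0.223 with an estimated correlation, within block 4 median 0.0877). Of 3 red blood cell genes 2 were lower. A total of 3 passed adjusted over the list alone (median -1.58, camera adjusted p = 0.000166, adjusted p = 0.0916 with an estimated correlation, within block 4 median -0.932). Of 13 fasting lipid genes 4 were higher and 0 lower. When adjusted over the list alone, the number was 6 (median 0.03, camera adjusted p = 0.0108, adjusted p = 0.053 with an estimated correlation, within block 4 median 0.0613). Of 12 oligodendrocyte genes 2 were lower and 0 higher. The count adjusted over the list alone was 3 (median -0.12, camera adjusted p = 0.0241, adjusted p = 0.889 with an estimated correlation, within block 4 median -0.152). That call ended without GLP1/Dexa 3, 5 or 6 (adjusted p = 0.112, 0.143 and 0.0659) or weight clamped 3 or 6 (0.0540 and 0.105). The number of genes was 27 within block 4, 24 of them among the 1592 (1510 at an unadjusted p under 0.05), and 26 with the series of library numbers as a covariate (1406 at an unadjusted p under 0.05). Without GLP1/Dexa 3 or 4 or weight clamped 2 it was 782, 896 and 997.

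Whether the conjugate departs from the sum of its parts was tested as the GLP1/Dexa effect minus the GLP1 and Dexa effects, on the log2 scale. The p53-inducible gene Trp53inp1 lay below the sum (-0.60 ± 0.0739, adjusted p = 3.9e-05), as did Hmcn1 (-0.77 ± 0.125, adjusted p = 0.00278) and Nfkbia (-0.79 ± 0.131, adjusted p = 0.0033). Sox9 (0.65 ± 0.0849, adjusted p = 8.72e-05) and Cldn5 (0.71 ± 0.115, adjusted p = 0.00278) lay above it. Sgk1 did not pass (-1.06 ± 0.226, adjusted p = 0.0532). With the block term Trp53inp1 and Nfkbia passed (adjusted p = 0.0367 and 0.0443). Sox9 (0.56), Cldn5 (0.78) and Hmcn1 (-0.85) did not (0.0742, 0.0714 and 0.0601). With joined blocks Sox9 and Cldn5 passed (0.00435 each) and Hmcn1 did not (0.0795).

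In this test 30 genes passed, 13 above and 17 below the sum, with a median departure of 1.39-fold. Of 17 cholesterol synthesis genes 1 lay below and 0 above. The number adjusted over the list alone was 9 (median -0.16, camera adjusted p = 3.28e-09, adjusted p = 0.143 with an estimated correlation, with the block term 0.00357). Of 35 glucocorticoid-induced genes 3 lay below and 0 above, and adjusted over the list alone 3 lay above and 11 below (median -0.10, mean 0.01, of opposite sign, camera adjusted p = 0.00107, adjusted p = 0.895 with an estimated correlation, with the block term median -0.18, adjusted p = 1.47e-07). Heat shock genes lay above the sum (median 0.18, 0 passed, 6 adjusted over the list alone, camera adjusted p = 7.39e-05, adjusted p = 0.684 with an estimated correlation, with the block term 0.00156), as did immediate-early genes (median 0.24, 0 passed, 1 adjusted over the list alone, camera adjusted p = 0.00146, adjusted p = 0.684 with an estimated correlation, with the block term 0.0290).

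The unfolded protein response list lay above the sum too (median 0.07, 0 passed, 1 adjusted over the list alone, camera adjusted p = 0.00927, adjusted p = 0.868 with an estimated correlation), but not with the block term (0.644) or without GLP1/Dexa 4 (0.0701). Oligodendrocyte genes (median -0.20, 0 passed, 0 adjusted over the list alone, camera adjusted p = 0.00146, adjusted p = 0.895 with an estimated correlation, with the block term 0.0129) and red blood cell genes (median -0.81, 0 passed, 0 adjusted over the list alone, camera adjusted p = 0.0339, adjusted p = 0.868 with an estimated correlation, with the block term 0.0447) lay below it. The red blood cell call ended without vehicle 3, 4 or 6 (adjusted p = 0.0892, 0.0705 and 0.0676), GLP1 1 or 3 (0.0657 and 0.0669), Dexa 6 (0.0709) or GLP1/Dexa 2, 3 or 5 (0.0576, 0.0652 and 0.1). With the block term 7 genes passed, 5 of them among the 30 (1293 at an unadjusted p under 0.05), and with blocks 2 and 3 joined 12, 10 of them among the 30. Without vehicle 6 the number was 46, without GLP1 1 or 2 it was 65 and 74, without Dexa 1, 2 or 6 it was 46, 17 and 51, and without GLP1/Dexa 3 it was 16.

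GLP1/Dexa and Dexa shared 602 genes that rose against vehicle and 78 that fell, against 52.9 and 7.53 for independent lists of those sizes, and GLP1/Dexa and GLP1 shared 144 and 40, against 9.96 and 1.57. Fold changes across genes, which are not independent replicates, correlated at r = 0.698 and 0.704. Unchanged groups that shared a simulated vehicle group gave r = 0.5 and 0.504 and 0 shared calls. Because vehicle was simulated too, these values leave out any peculiarity of the real vehicle libraries, which all comparisons with vehicle share. The simulated groups carried no block difference, whereas most GLP1, Dexa and GLP1/Dexa libraries lie in blocks 2 and 3 and all vehicle libraries in block 1, so r and the shared numbers can include a difference between blocks. The covariances were 0.0385 and 0.0352 against simulated values of 0.0140 and 0.0139, differences of 0.0245 and 0.0213. With the vehicle libraries split 3 and 3 the shared numbers were 46.6 higher and 3.70 lower for Dexa and 18.6 and 4.20 for GLP1, with r = 0.252 and 0.231. GLP1/Dexa and weight clamped mice shared 84 and 100 genes, against 17.9 and 11.6 for independent lists, with r = 0.424 against a simulated 0.503, covariances of 0.0218 and 0.0139, and 8.90 and 11.6 shared genes at r = 0.0307 with split vehicle libraries.

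GLP1 and Dexa shared 117 genes that rose and 31 that fell, against 8.69 and 0.864 for independent lists (r = 0.699 against a simulated 0.491, covariances 0.0338 and 0.0137). GLP1 and weight clamped mice shared 24 and 21, against 2.93 and 1.33 (r = 0.518 against 0.498, covariances 0.0233 and 0.0138), and Dexa and weight clamped mice shared 78 and 110, against 15.6 and 6.40 (r = 0.465 against 0.492, covariances 0.0231 and 0.0138). With split vehicle libraries these pairs had r = 0.212, 0.0601 and 0.0463.

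Tissue markers were compared as mean log2 CPM per library by exact 2-sided permutation tests of 6 against 6 libraries. The red blood cell mean was 1.61 ± 0.44 in GLP1/Dexa and 2.91 ± 0.66 in vehicle (SD, exact p = 0.00216, the smallest possible; adjusted p = 0.0736 over 68 tests). Against Dexa and against weight clamped mice it was also lower (exact p = 0.00216 each; adjusted p = 0.0552 over 51 tests). Astrocyte markers averaged 7.39 in weight clamped mice and 7.48 in vehicle (exact p = 0.00216, adjusted p = 0.0736), and 0 of the marker comparisons passed adjustment.

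Several lists passed in 0 of the 8 comparisons with camera. Their smallest adjusted p was 0.0733 for pituitary markers, 0.0921 for endothelial markers and 0.0921 for neuronal markers, 0.105 for striatal markers and 0.105 for incretin and glucagon receptors, 0.112 for interferon genes, 0.117 for thalamic markers, 0.119 for the stress axis, 0.169 for meningeal fibroblasts, 0.203 for anorexigenic and 0.324 for orexigenic signals. It was 0.249 for mural cells, 0.484 for inflammation, 0.680 for ependyma with tanycytes and 0.680 for pituitary control peptides, and 0.749 for hypothalamic regions. Over 256 list tests the median, the mean and the direction of the test differed in sign in 40, of which 1 passed.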

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

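The tests of library number blocks, GC content, cortex tissue and neutrophils were chosen only after the results were seen.

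Levels of 16 measures were searched in each of the 5 groups for a library whose distance to its nearest neighbour took most of the range of the group. Chance gives about 1 in 20 groups, 4 of the 80 searched, and 13 were found. Pomc stood at 186 CPM in GLP1/Dexa 6 (next library 35.7 CPM; pituitary markers were also highest there, at 1.83 log2 CPM), at 66.0 CPM in Dexa 4 (next 39.7 CPM) and at 23.2 CPM in vehicle 6 (next 35 CPM). Hbb-bs stood at 60.1 CPM in vehicle 2 (next 24.2 CPM), Lcn2 at 0.794 CPM in Dexa 3 (next 0.229 CPM), Glp1r at 3.25 CPM in weight clamped 2 (next 2.66 CPM) and Zfp871 at 5.95 CPM in vehicle 6 (next 2.68 CPM).

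Tissue markers and depth gave the remaining libraries of this kind. Cortex and hippocampus markers averaged 4.29 log2 CPM in vehicle 2 (next 2.59). Choroid plexus markers averaged 5.10 in GLP1 1 (next 1.60) and 3.59 in GLP1/Dexa 4 (next 1.32), and astrocyte markers 7.50 in GLP1/Dexa 1 (next 7.44). Gene reads numbered 43.0 M in GLP1 2 (next 40.3 M) and 29.1 M in Dexa 1 (next 36.5 M).

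The conjugate departed from the sum of its parts in 30 genes, led by Trp53inp1, Sox9, Cldn5, Hmcn1 and Nfkbia. With the block term 7 genes passed, 5 of them among the 30. Sox9, Cldn5 and Hmcn1 did not, but Sox9 and Cldn5 did with joined blocks. Reads in no gene numbered 1.001 per gene read in GLP1/Dexa and 0.9951 in vehicle (exact 2-sided permutation p = 0.00216, adjusted p = 0.0173 over 8 tests). Against vehicle weight clamped mice had adjusted p = 0.0450, Dexa 0.0491 and GLP1 0.0915. Within GLP1 the ratio was 0.9951 and 0.9958 in block 1 and 0.9968 to 1.0001 in block 2, so blocks may contribute.

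The genes that rose in Dexa may in large part reflect the block of library numbers and not the drug. Across these 930 genes the GLP1 libraries of block 2 lay above those of block 1 by a median of 0.201, with 890 genes higher, close to the pooled Dexa difference of 0.244. GLP1/Dexa libraries of block 3 lay above that of block 4 by 0.237, and Dexa libraries of block 3 differed from those of block 2 by -0.03. The division into blocks was itself made after seeing these libraries. GC content as the whole cause is argued against, since with GC offsets the median was 0.181 and 467 of these genes still passed. An effect of dexamethasone on these genes stays open, because Dexa and vehicle share no block and a block term compares them only through GLP1 libraries, 2 of which lie in block 1.

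The rise of glucocorticoid-induced genes in GLP1 may be a biological response of the hypothalamus, directly or through stress hormones, which were not measured in these data. A block effect is argued against, since within block 1 the median was 0.353, with 34 of 35 genes above 0 and 9 passing. GC content is argued against, since with GC offsets the median was 0.232 (camera adjusted p = 1.13e-33). Cortex tissue in vehicle 2 is argued against, since without that library the median was 0.279 (camera adjusted p = 2.75e-31). Only GLP1 1 and 2 lie in block 1, so the within-block values rest on these libraries, and the order of dissection is not recorded.

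The rise of Lcn2 in GLP1/Dexa may come from cells of the brain or its vessels that respond to the conjugate. A block effect is argued against only as the whole cause, since within block 3 Lcn2 was higher by 5.23 ± 1.18, although this did not pass over all genes (adjusted p = 0.110; 5 against 2 libraries). The 4.77 ± 0.920 within block 4 compares 1 library with 6 and takes its spread from other groups. Neutrophils, which carry much Lcn2, are argued against: over the mean of the other 4 groups their abundant genes S100a8 and S100a9 together rose by 0.332 CPM and Lcn2 by 6.44 CPM. Against vehicle both were lower, S100a8 at 0.516 and 0.591 CPM and S100a9 at 0.644 and 1.02 CPM. Of 10 neutrophil markers 4 were detected well enough to be tested, and the tissue itself expressed Csf3r (9.94 CPM in GLP1/Dexa, 9.39 CPM in the other groups) and Mmp9 (3.17 and 2.87 CPM). The wide range between the 6 GLP1/Dexa libraries, 0.690 to 16.8 CPM, stays unexplained.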

How the results depend on the processing

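The GC offsets, the block terms and the fit without vehicle 2 and GLP1/Dexa 6 were chosen only after the results were seen.

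With RLE size factors the 161 named gene values kept their direction and their side of the threshold, as did 160 with non-robust dispersions, all 157 still tested with a filter of 1 CPM in 6 libraries, 155 with no filter, 154 with DESeq2, 151 with 1 surrogate variable, 148 with GC offsets, 146 with limma voom, 144 without vehicle 2 and GLP1/Dexa 6, 124 with only the groups compared, 109 with the library number series, 56 with blocks 2 and 3 joined and 47 with the block term. Values that changed sign with no call in either fit numbered 2 with the surrogate variable, 6 with GC offsets, 4 without the 2 libraries, 3 with the series, 10 with joined blocks and 8 with the block term. Of 54 list calls 53 were kept with GC offsets, 52 with the surrogate variable, 49 without the 2 libraries, 38 with joined blocks, 33 with the block term, 31 with the directional fry test and 11 with an estimated correlation.

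Numbers of changed genes moved more than 1.5 times in some settings. The cause was not tested, except that fewer libraries entered some fits. With only the groups compared they were 698 for GLP1/Dexa and 37 for GLP1 against vehicle, 0 for GLP1/Dexa against GLP1 (1265 at an unadjusted p under 0.05 in edgeR) and 66 against Dexa. With no filter GLP1 had 154. With the library number series GLP1 had 432, weight clamped mice 2, and GLP1/Dexa against weight clamped 26. DESeq2 gave 526 for GLP1, and for GLP1/Dexa 37 against GLP1, 313 against Dexa and 140 beyond the sum. GC offsets gave 718 for Dexa and 5 for GLP1/Dexa against GLP1, and leaving out vehicle 2 and GLP1/Dexa 6 gave 5 there too.

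With the block term edgeR called 0 genes against vehicle in GLP1/Dexa, Dexa and weight clamped mice and 0 between GLP1/Dexa and GLP1 (1007, 1044, 1371 and 944 at an unadjusted p under 0.05), 28 in GLP1, 5 against Dexa (0 of the 150 called without blocks), 27 against weight clamped and 7 beyond the sum. With joined blocks it called 0, 0 and 2 (others than the 744) in the former 3 and 0 against GLP1 (1147, 1010, 945 and 1042 at an unadjusted p under 0.05), 28 in GLP1, 26 against weight clamped and 12 beyond the sum. In these fits only GLP1 has libraries in a block with vehicle. By chance alone a share of 0.05 of the 18737 tested genes has an unadjusted p under 0.05, near the lower of these numbers. Over the genes called without blocks, changes with the block term were a median of 0.517 times those without it in GLP1/Dexa, 0.296 in Dexa and 0.969 in weight clamped mice against vehicle. Standard errors were 2.25, 1.67 and 3.01 times as large. For the 3 genes of GLP1/Dexa against GLP1 the ratio was 0.689, and 1 with joined blocks.

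Numbers of lists that passed were 4, 7, 6 and 13 against vehicle in GLP1/Dexa, GLP1, Dexa and weight clamped mice, and 5, 4, 8 and 7 for GLP1/Dexa against GLP1, Dexa, weight clamped and the sum. The block term gave 7 for GLP1/Dexa, 12 for Dexa and 13 beyond the sum, and joined blocks 11, 11 and, against GLP1, 2. An estimated correlation gave 0, 1, 0, 6, 0, 0, 4 and 0, in the same order. The directional fry test gave 2 for GLP1, 0 for GLP1/Dexa against GLP1 and 1 beyond the sum, and the mixed fry test 8 for GLP1/Dexa and 2 against GLP1. Fry asks whether the members of a list move, not whether they move more than other genes.

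Some values reversed, and the cause was not tested. Choroid plexus markers in Dexa turned upward with the block term (adjusted p = 0.174) and with joined blocks (0.280). With that term the camera test of oligodendrocyte and clock genes in GLP1/Dexa against GLP1 pointed upward (0.615 and 0.816), the median of clock genes staying at -0.013. Klhl11 in Dexa was at -0.062 and -0.087 log2 units with the block term and joined blocks, Cstad in weight clamped mice at -0.078 with the block term, and Kcna3 in GLP1/Dexa against weight clamped at -0.77 with either block term and with the library number series.

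With vehicle libraries split 3 and 3, GLP1/Dexa shared 18.6 rises and 4.20 falls with GLP1 (r = 0.231), 46.6 and 3.70 with Dexa (r = 0.252) and 8.90 and 11.6 with weight clamped mice (r = 0.0307). GLP1 shared 7.15 and 2 with Dexa (r = 0.212) and 1.45 and 2.65 with weight clamped mice (r = 0.0601), and Dexa shared 5.05 and 6.95 with weight clamped mice (r = 0.0463). Each part of the vehicle group has 3 libraries, so fewer genes pass. Among genes of at least 1 CPM the undivided correlations of GLP1/Dexa were 0.785 with GLP1 and 0.768 with Dexa.

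Leaving out 1 library gave 815 to 2008 changed genes in GLP1/Dexa, 58 to 635 in GLP1, 684 to 1485 in Dexa and 427 to 778 in weight clamped mice against vehicle. It gave 3 to 9 between GLP1/Dexa and GLP1, 65 to 273 against Dexa, 782 to 2088 against weight clamped and 16 to 74 beyond the sum. Lists numbered 4 to 7, 5 to 9, 4 to 7 and 11 to 15 against vehicle, and 3 to 7, 4 to 5, 7 to 10 and 6 to 8 in the others. Of the named gene values 1821 were kept, 27 changed sign with no call, 132 lost their call and 12 gained one. No paired analysis was possible because replicate numbers pair nothing. What sequencing depth limits was not tested.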

Other observations

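The test of reads on the opposite strand was chosen only after the result was seen, and the tests of other splits of the samples before.

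About as many reads fell in no gene as in genes. The kit does not mark strand, and the reads may have been counted by strand, which would leave those of the opposite strand without a gene. In 139 pairs at least 90% of the exon length of a gene lay within exons of 1 gene on the opposite strand. The inner gene had a median read density of 1.09 relative to the outer gene (quartiles 0.0610 and 2.63). Reads were present in 120 of the inner genes, 34 of the pairs lay within 2-fold, and the densities correlated at a Spearman rho of 0.431. Strand-based counting would give inner genes about the density of the outer gene at the same position or above. The ratio used the mean density of the whole outer gene, so the lower quartile cannot decide this. The overlaps come from a newer annotation than that of the counts, so the cause stays open.

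Each comparison was repeated over 100 splits of the same libraries, the real split included, with libraries exchanged freely between blocks. In the comparisons with vehicle at most 2 of 100 splits, the real one included, gave as many changed genes as the real one. The groups lie largely in different blocks, so a split can stand out through blocks alone. These numbers show that the real groups differ more than random ones, but not whether treatment or block is the cause. For GLP1/Dexa 1 of 100 splits reached the real 1572 genes (highest other 504), for GLP1 1 of 100 reached 233 (highest other 18) and for weight clamped mice 1 of 100 reached 744 (highest other 1). For Dexa 2 of 100 splits reached 1209, and the highest other, at 1363, exchanged vehicle 6 and Dexa 1, which points to a structure of the samples.

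For GLP1/Dexa against GLP1 3 of 100 splits reached 3 genes, and the highest other, at 63, set GLP1 1 and 2 and GLP1/Dexa 1, 2, 5 and 6 against the rest. That split puts the libraries of blocks 1 and 4 on the same side, a structure of the samples, and edgeR called 0 genes with a block term (944 at an unadjusted p under 0.05) or with only these groups (1265 at an unadjusted p under 0.05), where without these changes limma voom called 2 and DESeq2 37. The other comparisons carry the same limit. For the sum, libraries were exchanged among all its groups, which also removes the GLP1 and Dexa effects. Those splits test for no effect at all and cannot exclude chance for the 30 genes. Against Dexa 1 of 100 reached 150 (highest other 119), against weight clamped mice 1 of 100 reached 1592 (highest other 571) and for the sum 2 of 100 reached 30. The highest other for the sum, at 83, moved libraries of vehicle, GLP1, Dexa and GLP1/Dexa, and its cause was not tested.

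For the numbers of lists that passed, chance cannot be excluded. The medians over the other splits were 7 lists for GLP1/Dexa, GLP1 and Dexa and 8 for weight clamped mice against vehicle, and 4, 4, 5 and 5 in the other comparisons. Against vehicle 88 of 100 splits reached the 4 lists of GLP1/Dexa (highest other 14), 57 the 7 of GLP1 (highest other 14), 70 the 6 of Dexa (highest other 15) and 12 the 13 of weight clamped mice (highest other 19). For GLP1/Dexa 43 reached the 5 lists against GLP1 (highest other 13), 60 the 4 against Dexa (highest other 14), 24 the 8 against weight clamped mice (highest other 14) and 40 the 7 for the sum (highest other 14).

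Fold changes correlated across genes with transcript GC content, Spearman rho being -0.271 in GLP1/Dexa, -0.303 in GLP1, -0.395 in Dexa and -0.101 in weight clamped mice against vehicle. For GLP1/Dexa rho was -0.0388 against GLP1, 0.141 against Dexa and -0.184 against weight clamped mice, and 0.324 for the sum. Genes are not independent replicates, so no p is given for these. Per library, the GC trend averaged 0.171 in vehicle, -0.0643 in GLP1/Dexa, -0.0540 in GLP1 and -0.158 in Dexa (exact 2-sided permutation p = 0.0281, 0.0281 and 0.0130, adjusted p = 0.0450 each over 8 tests), and 0.108 in weight clamped mice (adjusted p = 0.357). It also differed by block within groups. GLP1 1 and 2 of block 1 had 0.118 and 0.214, against -0.2155 to -0.0939 in block 2. GLP1/Dexa 6 of block 4 had 0.2165, against -0.278 to 0.0567 in block 3. In Dexa it varied within blocks, with -0.204 and 0.123 in block 3. The differences between groups can therefore reflect blocks, and these tests cannot tell the 2 apart.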
